A study of Mus musculus with 6 samples.

How the data were processed

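RNA sequencing libraries were made from whole brain tissue of mice, 6 in all, 3 labelled as control (sterile distilled water through the nose) and 3 labelled as PS (polystyrene nanoplastics), each with 28 days of exposure. Total RNA was extracted with TRIzol and libraries were built with the VAHTS Universal V6 kit, per the labels' protocols. Samples were assigned to groups from their labels, and all 6 were used.

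The authors deposited 1 table of FPKM values per library, that is, fragments scaled by gene length and by the reads of the library. Fastp, HISAT2, HTSeq, R 3.2.0 and the mouse build GRCm39 are named in the submitters' processing notes, which give no order or settings, so the strand setting of the counting is not given in the sources used here. Overlapping genes, antisense pairs and near-identical copies are therefore uncertain. The reference used here is of another build, so no nuclear coordinates are given, and it served only to look up mitochondrial gene lengths and, by exact words of 50 bases, copies of mitochondrial genes among annotated nuclear transcripts. Mitochondrial genes were matched to the symbols of the files by their protein names.

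The FPKM values moved in whole steps. For each library the total and the gene lengths that make the values whole read numbers were searched for, and 99.99% of the 26556 genes above 0 in at least 1 library came out whole in every library, within 0.02 reads. The recovered lengths of the mitochondrial genes equalled the annotated ones, for example 1545 bases for COX1. The totals behind the values were 39239183 to 40335590 reads, and the genes summed to 99.54 to 99.56% of them. These reads measure depth only; the main tests used FPKM. Replicates of a group differed by far more than sampling noise, with a chi-square per degree of freedom of 10.47 to 40.91 between libraries of a group, so none was treated as a copy of another.

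Genes with a mean FPKM of at least 1 over the 6 libraries were kept, which left 12229 and removed 15149. Values were taken as log2(FPKM + 1), with no rescaling between libraries, and the groups were compared with limma 3.58.1 in R 4.3.3 (linear model with group only, moderated with a variance trend, two-sided, 4 residual degrees of freedom). P-values were adjusted by the Benjamini-Hochberg method over the tested genes, and a gene was called at an adjusted p under 0.05. An exact permutation test of 3 against 3 cannot go below p = 0.1, so none was used for single genes.

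For groups of genes, 45 lists were fixed from general knowledge before the data were examined, along with the tests and the naming rule. They cover ALS and TDP-43 biology, stress and inflammation, respiration, cell types, brain regions and other tissues that whole brain can hold. Each list with at least 3 tested members, 44 in all, was tested with limma's camera at a preset correlation of 0.01 between members, adjusted over lists. Camera compares a list with all other genes. The tests were repeated with the correlation estimated from the data, and with fry, which asks whether the members move one way on balance. Counts adjusted over the list alone use the Benjamini-Hochberg method within a list. Some genes belong to several lists.

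Genes were named by a fixed rule. It took up to 12 called genes per direction with the largest log2 fold change and no overlap between groups. Where fewer than 12 of a direction were called, it added uncalled genes with no overlap, a log2 fold change of at least 0.5 and the lowest unadjusted p. It took up to 4 members of each list with the lowest unadjusted p, and Tardbp, Gfap, Aif1, Nefl and Hmox1 whatever their values. Predicted genes and clone names were passed over, and 1 gene that the rule names is not reported here.

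Both groups number their samples 1 to 3, and the labels do not say whether a number links samples. Deviations from the group means correlated between same-numbered libraries at 0.181, 0.185 and 0.161. All 3 exceed the 0.1 set beforehand, and no other matching of the numbers had a mean above 0.033, against 0.176. Such a pairing would come from the data and not from the labels. With only 6 possible matchings the numbered one can rank highest by chance, so the pairing is not established. A fit with the number as a block was run beside the main one, and its value is printed where it changes a call.

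Alternatives were other pseudocounts, filters, rescalings, variance models, sample weights, the block, each library left out in turn, and a rule of unadjusted p under 0.05 with a fold of at least 1.5. After seeing the data, limma-voom on the recovered reads and rescaling to the total without mitochondrial genes were added. The planned count test on recovered reads was not run, and voom took its place. The pipeline was tested on simulated data for PS against control, with 12187 genes of which 194 were changed. It called 100% of 2-fold and 98.9% of 1.5-fold changes, 9.81% of its calls were unchanged genes, and it made 0 calls when no gene was changed. The share of unchanged genes lay above the threshold of 0.05. The simulation gave every gene the same dispersion, 0.00437, and no shifts shared by the genes of a library. The shares called may therefore not hold for the real data. Tables were read with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.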

Results

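Gene expression was measured by RNA sequencing in whole brains of male C57BL/6J mice, a standard inbred laboratory strain. Mice of the PS group were given polystyrene nanoplastics, plastic particles found as an environmental pollutant, through the nose for 28 days. Control mice were given sterile distilled water by the same route for the same time. Each group held 3 libraries. The reads behind the deposited FPKM values numbered 39694248, 39239183 and 39632748 in control replicates 1, 2 and 3, and 40033806, 40335590 and 40015627 in PS replicates 1, 2 and 3. Each library listed 27378 genes, of which 22153 to 22698 were above 0. The labels number the samples within each group without saying that each came from a separate animal, so the p-values measure the spread between these samples, which may be partly technical. Correlations of log2 values between libraries ran from 0.9888 to 0.9966. Control replicate 2 lay apart from the other 5 libraries on the first principal component, which held 42.3% of the variance. Below, levels are mean FPKM ± SD with n = 3 per group, and log2 fold changes are PS over control on the log2(FPKM + 1) scale, which understates the change of low genes.

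The series is about TDP-43, an RNA-binding protein that collects in aggregates in amyotrophic lateral sclerosis (ALS), so its gene was examined first. Tardbp, which encodes TDP-43, stood at 18.8 ± 0.717 FPKM in control and 18.83 ± 0.385 in PS brains. Its log2 fold change was 0.003 with a standard error of 0.057 and a 95% interval from -0.126 to 0.131 (limma adjusted p = 0.997). Its sign turned with the setting, to -0.04 with sample weights, -0.03 without control replicate 3, -0.01 without PS replicate 1 and -0.004 after rescaling to the total without mitochondrial genes. None of 32 ALS-linked genes tested passed the threshold, over all genes or adjusted over the list alone, and their log2 fold changes lay between -0.15 and 0.16. The lowest unadjusted p among them belonged to Anxa11, at 12.74 ± 0.66 FPKM in control and 14.37 ± 0.891 in PS (log2 fold change 0.16, adjusted p = 0.824). The list as a whole was not called (camera adjusted p = 0.935). Nor were 23 stress granule components, the proteins of RNA-protein condensates formed under stress (adjusted p = 0.47, log2 fold changes from -0.15 to 0.11). Among 11 tested neuronal genes with long introns that depend on TDP-43, the lowest was Csmd1 (log2 fold change -0.28, adjusted p = 0.844), and the list was not called (camera adjusted p = 0.47) except without control replicate 2 (median 0.07, adjusted p = 0.00963). RNA levels do not measure where TDP-43 protein lies or whether it aggregates.

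Of 12229 genes tested, 20 were called, and all 20 were lower in the PS brains. With all 6 libraries and the filter, no gene was called higher by limma on log2 FPKM without block or weights, nor by limma-voom on recovered reads. In other fits 3 were with the replicate block, 297 with sample weights and 1, near the floor of the values, with no filter. At an unadjusted p under 0.05, 325 genes were higher and 402 lower, where chance gives 611 in both directions together. Sgk1, a kinase induced by glucocorticoids, fell from 62.67 ± 5.86 to 35.54 ± 1.82 FPKM (log2 fold change -0.80, SE 0.078, adjusted p = 0.00937). Ddit4, an inhibitor of mTORC1 signalling induced by hypoxia and glucocorticoids, fell from 65.73 ± 6.99 to 31.84 ± 6.11 (log2 fold change -1.03, SE 0.127, adjusted p = 0.0176). Lcn2, an iron-siderophore-binding protein of the acute-phase response, fell from 10.18 ± 1.1 to 2.133 ± 0.772 (log2 fold change -1.86, SE 0.155, adjusted p = 0.00937). In all 20 genes the 3 PS values lay below the 3 control values. These genes were picked for their difference between the groups, so this separation is no added support. Over all tested genes 11.3% showed no overlap between groups, where chance gives 10%.

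**Figure D1:**
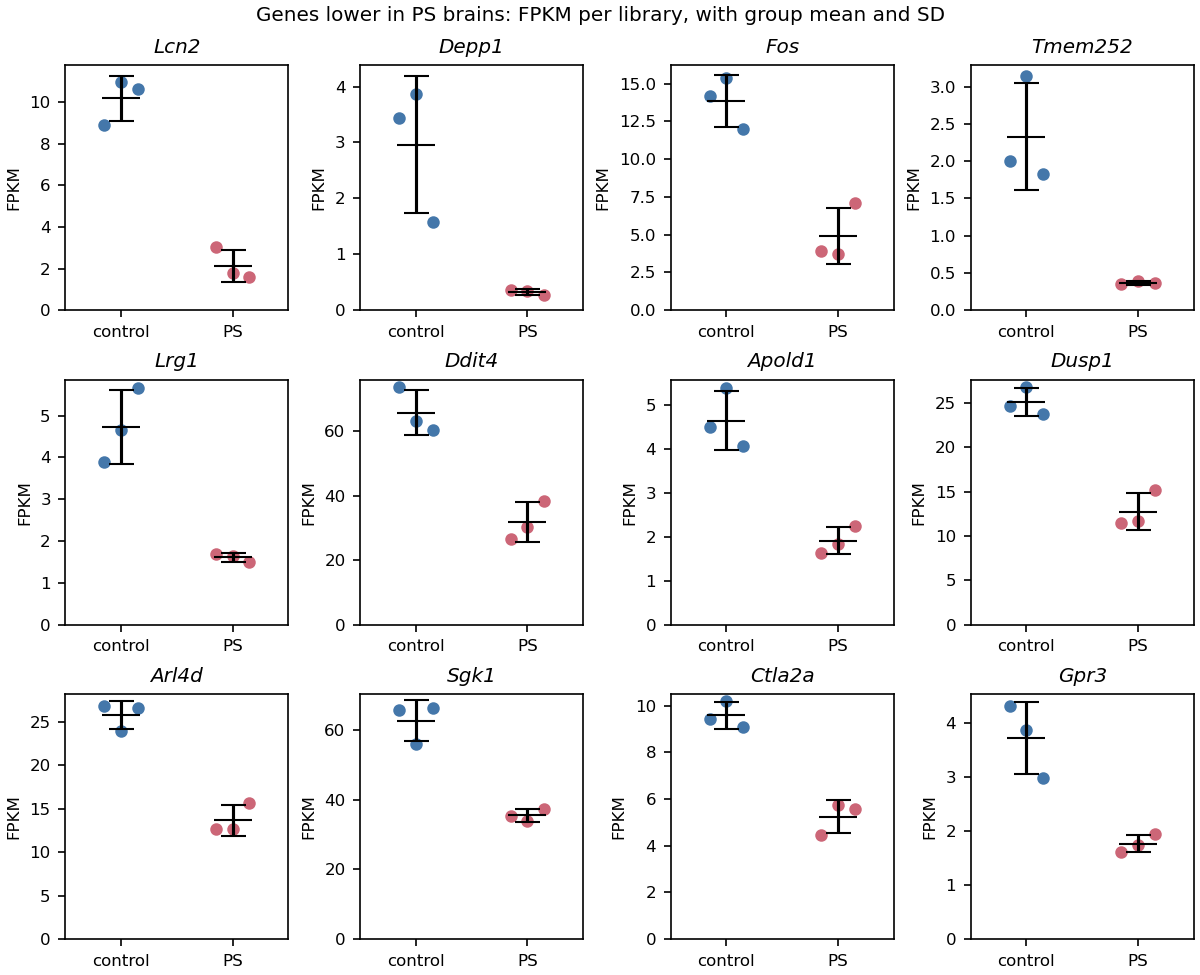
FPKM of the 12 called genes with the largest log2 fold change, predicted genes passed over, per library (points) with group mean and SD, from 0 on each vertical axis. In each panel the 3 PS libraries lie below the 3 control libraries, which the naming rule required, as for Lcn2 at 10.18 against 2.133 FPKM.

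Of the fixed immediate early list, 2 genes were called. Fos, a transcription factor used as a marker of neuronal activity, stood at 13.87 ± 1.72 FPKM in control and 4.915 ± 1.87 in PS (adjusted p = 0.0334). Dusp1, a phosphatase that switches off MAP kinases, fell from 25.1 ± 1.56 to 12.77 ± 2.06 (adjusted p = 0.0119). Outside that list, the GTPase gene Arl4d fell from 25.77 ± 1.6 to 13.64 ± 1.73 (adjusted p = 0.0101), and the receptor gene Gpr3 from 3.723 ± 0.673 to 1.772 ± 0.165 (adjusted p = 0.0452). Vwf, which encodes von Willebrand factor and was the only endothelial list member called over all genes, fell from 5.802 ± 0.435 to 3.078 ± 0.218 (adjusted p = 0.0101). Apold1, known as an endothelial early-response gene but in none of the lists, fell from 4.654 ± 0.675 to 1.91 ± 0.307 (adjusted p = 0.014). Lrg1, an acute-phase glycoprotein also made by endothelium, fell from 4.732 ± 0.882 to 1.615 ± 0.106 (adjusted p = 0.00937). Ctla2a fell from 9.58 ± 0.563 to 5.249 ± 0.701 (adjusted p = 0.0153). Tmem252 and Depp1 were low in control, at 2.326 ± 0.717 and 2.961 ± 1.22 FPKM, and under 1 in PS, at 0.3677 ± 0.024 and 0.3216 ± 0.0496 (adjusted p = 0.0118 and 0.0317). Errfi1, a feedback inhibitor of the EGF receptor, fell from 19.52 ± 1.37 to 12.66 ± 0.637 (adjusted p = 0.0153). The other members were Angptl4, Dyrk3, Cebpd, Rasd1, Acer2 and LOC118567915, with log2 fold changes from -0.53 to -0.83. These 6 lie outside the naming rule and were named after their values were seen, to complete the set.

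The gene count depended on single libraries. Without PS replicate 2, 0 genes passed. Without control replicate 1 or PS replicate 1, 2 passed in each case, and without control replicate 3, 66 passed. All 20 stayed lower at an unadjusted p under 0.05 in those 4 fits. The 20 genes were chosen in these same libraries, so this is no independent check. Testing every gene above 0 left 1 call, which was none of the 20, a mean FPKM of at least 5 left 9, and sample weights gave 632. With the replicate number as a block, 48 genes were called, 45 lower and 3 higher. The 3 higher genes, named after their values were seen, were Cdc42ep1, Trim59 and the clock output gene Dbp, with log2 fold changes of 0.43, 0.41 and 0.49. The blocked adjusted p of Dbp was 0.0461. Genes with a low unadjusted p that were higher in PS by at least 0.5 on the log2 scale without overlap included P2ry13, Inmt, Grm7 and Sh2d5. Their adjusted p lay between 0.326 and 0.545, so these 4 did not pass in the main fit. Without control replicate 3, Grm7 and P2ry13 were called (limma adjusted p = 0.0117 and 0.0495), and with sample weights all 4 were.

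Immediate early genes were lower as a group. All 18 tested members had negative log2 fold changes, with a median of -0.54. Of these, 15 had an unadjusted p under 0.05, 2 (Fos and Dusp1) were called over all genes, and 13 were called adjusted over the list alone. Nr4a1, a nuclear receptor induced by activity, was at 12.35 ± 2.9 FPKM in control and 5.606 ± 1.08 in PS (adjusted p = 0.0626, and 0.0107 with the replicate block). Junb was at 31.35 ± 4.82 and 17.82 ± 2.68 (adjusted p = 0.0697, and 0.0107 with the block). Limma-voom on recovered reads, without the block, also called Nr4a1 and Junb (adjusted p = 0.0353 and 0.044). Camera called the list (adjusted p = 1.23e-23), but not with an estimated correlation between members (adjusted p = 0.182).

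Glucocorticoid-responsive and hypoxia-responsive genes were lower as well. Of 14 glucocorticoid-response genes, 12 were lower, 3 were called over all genes (Sgk1, Errfi1 and Ddit4) and 8 were called adjusted over the list alone (camera adjusted p = 1.07e-15). With an estimated correlation the adjusted p was 0.091. Cdkn1a, a cell cycle inhibitor held by this list and by the p53 list, was at 48.44 ± 5.73 FPKM in control and 30.3 ± 4.02 in PS (adjusted p = 0.0685, and 0.029 with the block). Of 13 hypoxia-response genes, 11 were lower, 1 (Ddit4) was called over all genes and 6 adjusted over the list alone (camera adjusted p = 4.1e-09). With an estimated correlation the adjusted p was again 0.091. The median of the hypoxia list, -0.33, was -0.22 without control replicate 1 and -0.19 without control replicate 2, with the list still called. Adm, the vasodilator peptide adrenomedullin, was at 2.646 ± 0.496 and 1.221 ± 0.203 FPKM (adjusted p = 0.0685, and 0.00527 with the block). The glycolytic regulator Pfkfb3 was at 8.716 ± 0.882 and 6.199 ± 0.348 (adjusted p = 0.139). Ddit4 is a member of both lists, so their counts are not independent.

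Vessel and blood-cell transcripts moved in the same direction. Of 16 endothelial and barrier markers, 13 were lower, Vwf was called over all genes, and 4 (Vwf, Slc2a1, Ly6c1 and Esam) were called adjusted over the list alone. Slc2a1, the glucose transporter of the blood-brain barrier, was at 90.65 ± 10.3 FPKM in control and 65.4 ± 5.54 in PS (adjusted p = 0.199). It is also a member of the hypoxia list, so the counts of these lists are not independent. The median of the endothelial list was -0.11 (camera adjusted p = 7.17e-06, and adjusted p = 0.36 with an estimated correlation). In the list of blood and infiltrating immune cells, all 10 tested members were lower and the 5 called adjusted over the list alone were red-cell genes, with none called over all genes. Hbb-bt, a beta globin, was at 18.73 ± 3.88 and 6.097 ± 2.65 FPKM (adjusted p = 0.0626, and 0.0155 with the block), and Hba-a1, an alpha globin, at 41.91 ± 9.23 and 18.34 ± 4.51 (adjusted p = 0.0685, and 0.026 with the block). Globin genes have near-identical copies, so the split of reads between them is uncertain. Hba-a2 and the heme synthesis gene Alas2 had log2 fold changes of -0.90 and -0.89 (adjusted p = 0.0751 for both, and 0.0264 and 0.0253 with the block). The list was called by camera (adjusted p = 1.5e-09) but not with an estimated correlation (adjusted p = 0.091). The mean log2 score of the red-cell genes, set to 0 at the control mean, was 0.21, 0.14 and -0.35 in the control libraries and -1.33, -1.32 and -0.76 in the PS libraries, so it separated the groups as the called genes did.

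Decreases were also called in lists in which 1 or 2 members passed when adjusted over the list alone. Among 12 p53 targets only Cdkn1a and Trp53inp1 were called adjusted over the list alone, and none over all genes (median -0.05, camera adjusted p = 0.00581, adjusted p = 0.36 with an estimated correlation). The median was -0.08 without control replicate 2 and -0.03 without PS replicate 1. Of 22 proinflammatory mediators, 7 were expressed enough to be tested. Of these, Nfkbia, an inhibitor of NF-kappaB induced by it and by glucocorticoids, was at 25.73 ± 3.43 FPKM in control and 14.28 ± 2.97 in PS (adjusted p = 0.0736, and 0.0224 with the block). It is also a member of the glucocorticoid list, so the counts of these lists are not independent. Nfkbia and Ptgs2 were called adjusted over the proinflammatory list alone, none over all genes. The proinflammatory list had a median of -0.22 (camera adjusted p = 0.0138, adjusted p = 0.36 with an estimated correlation). Without PS replicate 1 the list was not called (median -0.12, adjusted p = 0.126), and without PS replicate 3 the median was -0.11. Among 9 tested genes of reactive astrocytes, Lcn2 alone was called, and the list (median -0.09, camera adjusted p = 0.0306, adjusted p = 0.36 with an estimated correlation) was not called without control replicate 3 (-0.005, adjusted p = 0.174) or PS replicate 1 (-0.03, adjusted p = 0.159). Without control replicate 2 its median was -0.045. Gfap, the astrocyte intermediate filament, was at 38.64 ± 3.13 and 40.72 ± 3.34 FPKM (log2 fold change 0.07, 95% interval from -0.110 to 0.257, adjusted p = 0.978).

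Markers of the oligodendrocyte lineage were higher in PS as a group, with no single gene called. Of 11 oligodendrocyte precursor markers, 10 were higher, 7 had an unadjusted p under 0.05 and 6 were called adjusted over the list alone (median 0.23, camera adjusted p = 5.18e-08). With an estimated correlation the adjusted p was 0.091, and without control replicate 2 the median was 0.14 (camera adjusted p = 3.51e-07). Sox10, a transcription factor of the whole lineage, was at 11.62 ± 0.498 FPKM in control and 14.98 ± 0.2 in PS (log2 fold change 0.34, adjusted p = 0.0828). Enpp6, a marker of newly forming oligodendrocytes, was at 1.506 ± 0.335 and 2.31 ± 0.115 (adjusted p = 0.378), and Gpr17 at 7.361 ± 1.17 and 9.453 ± 0.427 (adjusted p = 0.565). All 15 markers of mature oligodendrocytes and myelin had positive log2 fold changes (median 0.25, camera adjusted p = 9.66e-09), and 1, Ugt8a, was called adjusted over the list alone. With an estimated correlation the adjusted p was 0.524. The mean scores of this list were 0.06, -0.31 and 0.24 in the control libraries and 0.27, 0.21 and 0.30 in the PS libraries, so control replicate 3 lay above PS replicate 2. Without control replicate 2, which stood apart, the median was 0.09 (adjusted p = 0.000252).

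**Figure D2:**
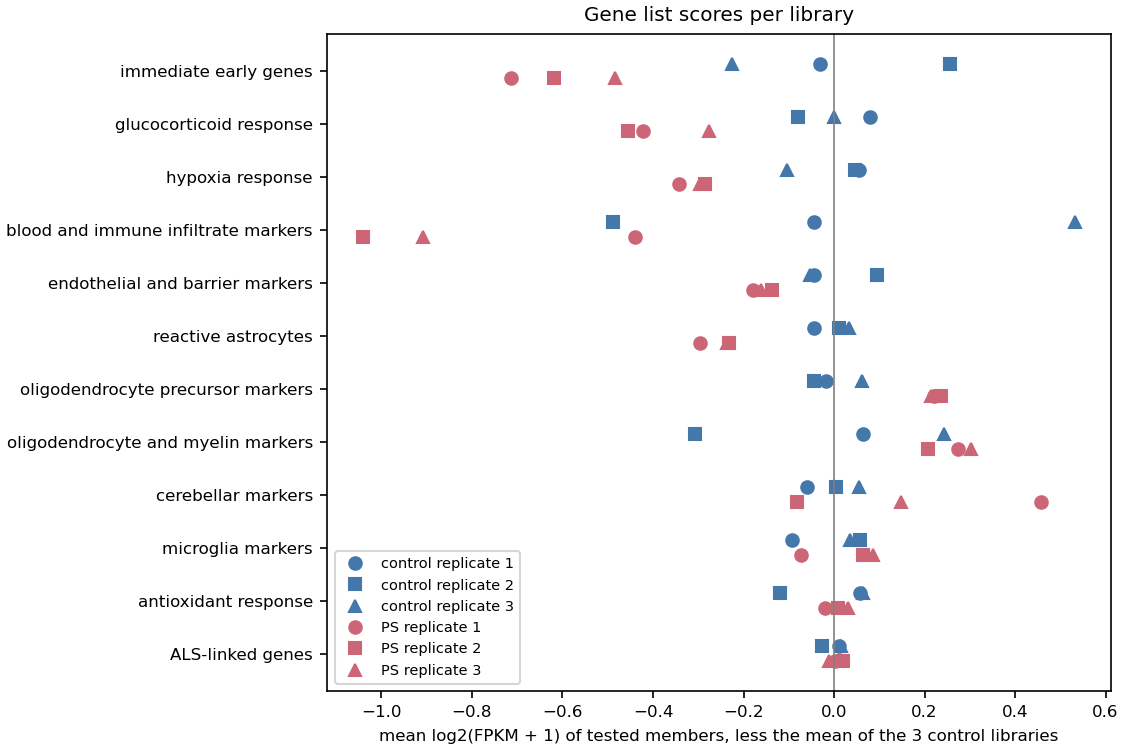
Mean log2(FPKM + 1) of the tested members of 12 gene lists in each library, less the control mean, with control and PS libraries marked apart. The 3 PS libraries lie below the 3 control libraries for immediate early genes and above them for oligodendrocyte precursor markers, while for blood and immune markers control replicate 2 (-0.49) lies below PS replicate 1 (-0.44).

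Markers of several brain regions and border tissues were also higher by camera, each by little, and none was called with an estimated correlation. All 15 cerebellar markers were higher (median 0.16, camera adjusted p = 1.43e-04, adjusted p = 0.865 with an estimated correlation), but without PS replicate 1 the median was 0.002 and the adjusted p 0.649. Among thalamic and midbrain markers, 11 of 12 were higher (median 0.19, camera adjusted p = 3.42e-04, adjusted p = 0.524 with an estimated correlation), and the call ended without PS replicate 1 (0.10, adjusted p = 0.0822), and the median was 0.08 without control replicate 2. The region score, a mean of these 2 lists, was highest in PS replicate 1, at 0.39 against -0.01 and 0.12 in PS replicates 2 and 3. Meningeal fibroblast markers (median 0.12, camera adjusted p = 0.00732, adjusted p = 0.932 with an estimated correlation) lost the call without control replicate 1 (0.07, adjusted p = 0.0774) or PS replicate 2 (0.03, adjusted p = 0.702). Choroid plexus markers (median 0.16, camera adjusted p = 0.0245, adjusted p = 0.937 with an estimated correlation) lost it without control replicate 2 (-0.03, adjusted p = 0.951), PS replicate 1 (0.01, adjusted p = 0.93) or PS replicate 3 (0.11, adjusted p = 0.0653). Ependymal markers (median 0.16, camera adjusted p = 0.0396, adjusted p = 0.937 with an estimated correlation) turned to -0.04 without control replicate 2 (adjusted p = 0.866) and lost the call without PS replicate 1 (0.15, adjusted p = 0.156) or PS replicate 3 (0.18, adjusted p = 0.0729). Cholesterol synthesis genes (median 0.08, camera adjusted p = 0.0489, adjusted p = 0.937 with an estimated correlation) turned to -0.01 without control replicate 2 (adjusted p = 0.781), and lost the call without control replicate 1 (adjusted p = 0.0593), PS replicate 1 (adjusted p = 0.135) or PS replicate 2 (adjusted p = 0.139). No member of these lists was called over all genes or adjusted over the list alone.

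Nuclear and mitochondrial genes of the respiratory chain gave different results. The 72 nuclear-encoded members had a median of 0.03 with none called over all genes or adjusted over the list alone (camera adjusted p = 0.0489, adjusted p = 0.99 with an estimated correlation, adjusted p = 0.0854 with the replicate block). Without control replicate 2 the median was -0.04 (adjusted p = 0.00421), and the call was lost without PS replicate 2 (0.01, adjusted p = 0.802) or PS replicate 3 (0.02, adjusted p = 0.317). Of the 13 genes encoded in mitochondrial DNA, 12 were lower, none was called over all genes and 3 were called adjusted over the list alone (median -0.18, camera adjusted p = 2.8e-08, adjusted p = 0.36 with an estimated correlation). Without control replicate 3 the median was -0.11. ATP6, a subunit of ATP synthase, was at 131.6 ± 10.6 FPKM in control and 70.28 ± 16.8 in PS (adjusted p = 0.0626, and 0.00164 with the block). ATP8 was at 25.22 ± 11.6 and 9.889 ± 2.73 (adjusted p = 0.327, and 0.00903 with the block), and COX2 at 124.5 ± 24.9 and 79.25 ± 20.1 (adjusted p = 0.486). COX3 was at 100.3 ± 51.4 and 96.91 ± 17.8 (log2 fold change 0.05) and ND3 at 110 ± 16.3 and 105.1 ± 6.9 (-0.06). The 6 genes from COX2 to ND4L were listed far below their neighbours, such as COX1 at 13160 ± 609 in control and 12190 ± 936 in PS. Of the 50-base words of COX2, COX3, ATP6, ND3 and ND4L, at least 98.0% also occur, for each gene, in annotated nuclear transcripts of the reference, so the values of these genes are uncertain. For ATP8 none was found in those transcripts, and for the other 7 mitochondrial genes 0.0 to 62.2%. Reads from mitochondrial genes made up 4.79, 4.88 and 5.41% of the reads in control and 4.32, 4.40 and 4.86% in PS.

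**Figure D3:**
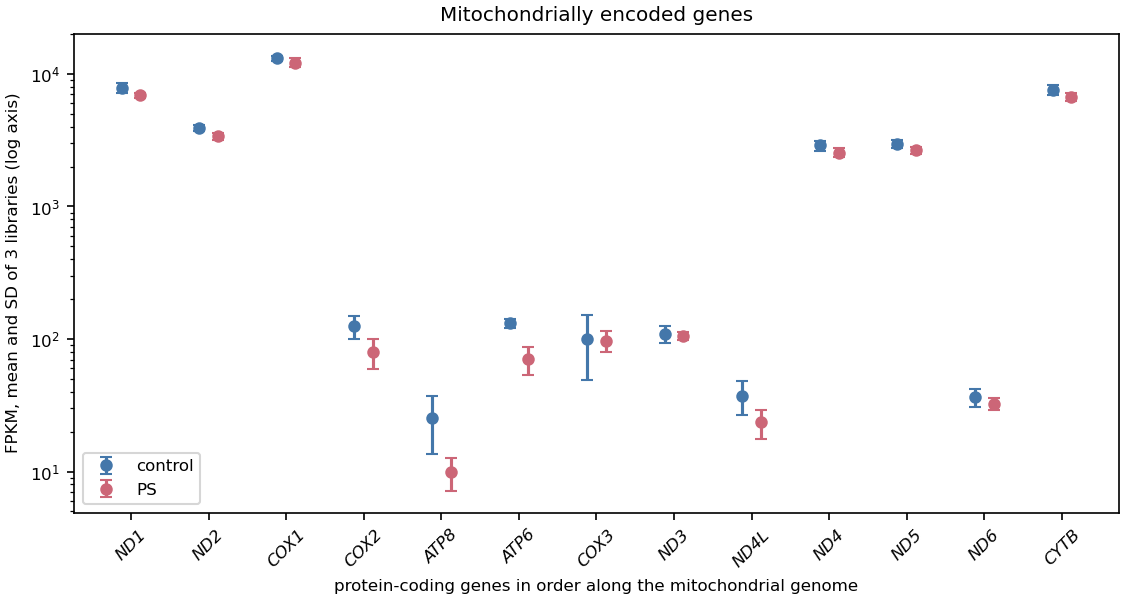
Mean FPKM with SD of the 13 mitochondrial genes in genome order, on a log axis, for 3 control and 3 PS libraries. The genes from COX2 to ND4L lie far below their neighbours, with ATP6 at 131.6 FPKM in control and 70.28 in PS against 13160 and 12190 for COX1.

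Other glial, neuronal and stress lists were not called in the unblocked, unweighted camera test of all 6 libraries, though some were under other settings. Microglia markers went both ways (camera adjusted p = 0.935), and Aif1, a general microglia and macrophage marker, was at 3.011 ± 0.148 FPKM in control and 2.4 ± 0.357 in PS (log2 fold change -0.24, 95% interval from -0.447 to -0.040, adjusted p = 0.751). Disease-associated microglia (adjusted p = 0.0899) were called without control replicate 3 (median 0.09, adjusted p = 0.0342) or PS replicate 1 (0.07, adjusted p = 0.00165), and astrocyte markers (adjusted p = 0.104) without control replicate 1 (0.07, adjusted p = 0.0151) or PS replicate 2 (0.08, adjusted p = 0.0024). Interferon-stimulated genes, mural cell markers, the antioxidant response and the unfolded protein and integrated stress response each gave an adjusted p of 0.971, with the antioxidant list called without control replicate 2 (-0.06, adjusted p = 0.0142). Hmox1, heme oxygenase 1, was at 3.225 ± 0.596 and 3.083 ± 0.0475 FPKM (log2 fold change -0.04, 95% interval from -0.273 to 0.195, adjusted p = 0.993), and its sign turned to 0.04 without control replicate 3. Autophagy and lysosome genes gave an adjusted p of 0.3. Heat-shock genes (0.222) were called with sample weights (0.000102) and without control replicate 2 (-0.04, adjusted p = 0.0165) or control replicate 3 (-0.02, adjusted p = 0.0342), and proteasome subunits (0.37) with quantile normalization (0.0449), sample weights (0.0429) and without control replicate 2 (-0.08, adjusted p = 1.46e-05) or PS replicate 2 (-0.05, adjusted p = 0.0286). Cytosolic ribosomal proteins (0.836) were called in opposite directions, without PS replicate 1 (0.07, adjusted p = 2.08e-08), control replicate 2 (-0.05, adjusted p = 0.00123) and PS replicate 3 (-0.04, adjusted p = 0.0196).

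Neuronal lists gave no call either in the unblocked, unweighted camera test of all 6 libraries. Nefl, the neurofilament light chain, was at 182.2 ± 35.1 FPKM in control and 181.5 ± 3.47 in PS (log2 fold change 0.01, 95% interval from -0.268 to 0.296, adjusted p = 0.996), and its sign turned with quantile normalization, sample weights and without control replicate 2 or PS replicate 1. The neurofilament and axonal list (camera adjusted p = 0.352) was called only without control replicate 1 (0.06, adjusted p = 0.0404). Synaptic genes (0.765), inhibitory neuron markers (0.935) and excitatory forebrain markers (0.971) were called only without control replicate 2, with adjusted p of 5.23e-06, 0.0413 and 0.0373. Monoaminergic markers (0.606) were called without control replicate 2 (adjusted p = 4.41e-05) and with sample weights (0.0044). Cholinergic and motor neuron markers (0.463) were called without control replicate 3 (adjusted p = 0.0342), hindbrain (0.364) and hypothalamic markers (0.971) without control replicate 1 (0.016 and 0.018), and striatal markers (0.971) without control replicate 1 (0.00106), PS replicate 1 (0.01) or with sample weights (7.61e-05). Olfactory bulb markers, from the region that receives input from the nose, had a median of -0.13 (adjusted p = 0.0774, and 0.00258 with the replicate block), and were called without control replicate 1 (0.00805), control replicate 3 (0.0342) or PS replicate 2 (0.000189). Nuclear-retained long noncoding RNAs had a median of -0.12 (adjusted p = 0.107, and 0.0416 with the block) and were called without control replicate 1 (0.00601) or PS replicate 3 (0.008). The median, the mean and the camera direction were not all of one sign for the monoaminergic, inhibitory, microglia, hypothalamic, striatal and antioxidant lists. Pituitary markers had 2 tested members and were not tested as a list.

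In all, 18 of 44 tested lists were called by camera with a preset correlation, 9 higher and 9 lower, and 0 with an estimated correlation, where 6 had an unadjusted p under 0.05. The rotation test fry called 3, the glucocorticoid, hypoxia and oligodendrocyte precursor lists (adjusted p = 0.0481 each).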

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

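The voom fit on recovered reads and the total without mitochondrial genes were chosen after seeing the data. All 20 called genes stayed lower in each fit that tested them, though these fits reuse the libraries in which the genes were chosen. Against 20 called genes, 15 to 29 were called with other pseudocounts, rescalings and variance models, voom, or the total without mitochondrial genes. With no filter 1 gene was called, higher in PS, and 0 lower. This gene lay near the floor, at 0 FPKM in each control library and at 0.121 to 0.122 in the PS libraries. A filter at a mean FPKM of 5 left 9, all lower, since fewer genes were tested. Sample weights, which gave control replicate 1 a weight of 6.01 and control replicates 2 and 3 weights of 0.33 and 0.35, called 632 genes, 335 lower and 297 higher. The replicate block called 48, 45 lower and 3 higher, and 44 genes had an unadjusted p under 0.05 and a fold of at least 1.5. Leaving out each library in turn gave 0 to 66 genes, 0 to 49 lower and 0 to 17 higher. Of the lists, 12 to 24 were called by camera in each fit with the preset correlation, 0 with an estimated correlation and 3 by fry. Beyond the genes and lists whose blocked values are printed, the block changed no other call among the genes named by the rule and the lists. Of the genes called with the block and not in the main fit, voom without the block called Nr4a1, Junb, Cdkn1a, Nfkbia, Hbb-bt and ATP6. It did not call Adm, ATP8, Hba-a1, Hba-a2, Alas2 or Dbp. Some genes changed sign and some called lists turned the direction of their test. With sample weights these were the nuclear respiratory chain (-0.006), choroid plexus (-0.087), Srgn (0.057), Mia (-0.026), Tardbp (-0.037) and Nefl (-0.181). Quantile normalization gave -0.014 for Nefl, and the total without mitochondrial genes -0.004 for Tardbp. With each library left out in turn, medians ranged from -0.038 to 0.078 for the nuclear respiratory chain, -0.014 to 0.137 for cholesterol synthesis and -0.036 to 0.345 for ependymal markers. Over the same fits Calml4 ranged from -0.058 to 0.508, Ccdc153 from -0.01 to 0.477, Tardbp from -0.027 to 0.024, Nefl from -0.152 to 0.126 and Hmox1 from -0.159 to 0.043. The cause of these shifts was not tested. Over all settings, 86 genes named by the rule for size, for called lists or whatever their values, with Tardbp left out, gave 1596 values. Of these, 1454 kept their direction and side of the threshold, 63 lost the call, 70 gained it and 9 changed sign. Only genes called in the main fit could lose the call, and most of the 86 were not called there. Of 918 list values, 801 kept the call or its absence, 75 lost it, 37 gained it and 5, all of called lists, turned the direction of the test. Only values of the 18 lists called in the main test could lose the call. Medians of lists near 0 changed sign in further fits. Libraries held 39239183 to 40335590 reads, and how depth limits the calls by expression level was not tested.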

Other observations

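Microglia markers and clock genes each held members that went opposite ways. Cx3cr1, the fractalkine receptor of resting microglia, was at 8.48 ± 0.849 FPKM in control and 11.31 ± 0.512 in PS, and the purine receptor gene P2ry13 at 2.249 ± 0.71 and 3.896 ± 0.43. Both were called adjusted over the list alone and neither over all genes (limma adjusted p = 0.22 and 0.358). The protease gene Ctss was at 52.28 ± 0.408 and 45.18 ± 6.24 FPKM (adjusted p = 0.819) and Trem2, a receptor of activated microglia, at 5.865 ± 0.17 and 7.523 ± 1.41 (adjusted p = 0.752). Among 16 clock genes, Dbp was at 23.59 ± 4.21 FPKM in control and 33.19 ± 1.24 in PS (adjusted p = 0.266), Cry1 at 8.364 ± 0.722 and 6.576 ± 0.21 (adjusted p = 0.356) and Per1 at 10.79 ± 1.26 and 8.582 ± 0.445 (adjusted p = 0.538). These 3 were called adjusted over the list alone, and the list as a whole was not called (camera adjusted p = 0.637). The labels give no time of day for tissue collection.

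All tests below were chosen after the result was seen. The first pattern is the 20 genes lower in PS. Of the 10 ways to split the 6 libraries 3 against 3, 1, the real one, called 20 genes and the highest of the others called 0, while 10 splits are too few for a share under 0.05. The same holds among the 4 splits that part all 3 number pairs, where the other 3 called 0. Residual blood in the control brains may lower such a set in PS. With the red-cell score as a covariate the mean difference of the 20 genes was -0.69 (SE 0.07), against -0.92 without it. This cannot decide on blood, because the score itself separated the groups and the 20 genes were picked for their difference in the same libraries. Immediate early genes differed by -0.61 on average (SE 0.16), so an acute difference between the animals at collection, in handling, anaesthesia or time of day, cannot be told apart from the exposure, because the labels give no collection order.

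The second pattern lies in the mitochondrial genes from COX2 to ND4L. Of these, ATP8, ATP6, COX2 and ND4L had log2 fold changes of -1.21, -0.92, -0.66 and -0.63, and ND3 and COX3 had -0.06 and 0.05. None was called in the main fit, while ATP6 and ATP8 were called with the block. Without the block, ATP6 was called by limma-voom on recovered reads (adjusted p = 0.0353). With sample weights, ATP6, ATP8 and COX2 were called (limma adjusted p = 0.00153, 0.0135 and 0.0212). Reads lost to a near-identical nuclear copy are a candidate explanation for the low level of the stretch in both groups: the 6 other genes of the heavy strand were listed 54.3-fold higher by median, and 5 of the 6 genes have nearly their whole sequence in nuclear transcripts. ATP8 has none in annotated transcripts, and the nuclear genome itself was not searched. Lower mitochondrial RNA in PS brains as a whole would lower the heavy-strand genes by about the same log2 amount. The 6 other heavy-strand genes had a median of -0.17 (SD over genes 0.03), against -0.64 over the stretch. That SD leaves out the spread between libraries, and the values of the stretch are uncertain, so the contrast does not settle the cause. Why only part of the stretch would differ between the groups stays open.

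The third pattern is the higher level of oligodendrocyte precursor markers. Control replicate 2 alone is argued against as the cause of the mean difference, since without it that difference was 0.20 (SE 0.03), against 0.22 with all 6 libraries. The median of the list fell by more, as given above. A different share of cerebellum or of thalamus and midbrain is argued against as well, since with the score of those regions as a covariate the difference was 0.22 (SE 0.05). Other brain regions were not in that score, so a different share of them was not tested. An effect of the exposure on the lineage remains a hypothesis, and other differences between the animals were not tested.

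For the count of called lists, 6 of the 10 splits of the libraries, the real one included, called at least the real 18. The other splits called 12 to 24 lists. The count of lists called by camera therefore does not set the real grouping apart from other groupings of these libraries. Splits with a camera p as small as the real one, itself included, numbered 2 for the myelin and the thalamic and midbrain lists, 5 for the cerebellar and meningeal lists, 6 for the choroid plexus, ependymal and cholesterol lists and 8 for the nuclear respiratory chain. For the other 10 called lists the number was 1, the real split, and 10 splits are too few for a share under 0.05.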
